A study of Mus musculus with 8 samples.

How the data were processed

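RNA from the ileum of irinotecan-treated mice was sequenced in bulk in 8 libraries, 4 from wild-type (WT) mice and 4 from Gsdme-deficient mice, here called Gsdme_KO. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was enriched by poly(A) selection and the libraries were strand-specific. The submitters' processing notes name HISAT2, SAMtools, featureCounts, Subread and DESeq2, and the genome build GRCm38. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of normalized signal, in which each gene's read count had been divided by 1 size factor per library.

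Whole reads were recovered from that table. All values (100%) in each of the 8 libraries came out as whole multiples of a single step per library, within a tolerance of 0.01 reads. Median-of-ratios size factors recomputed from these reads equalled the divisors, which ran from 0.821 to 1.33. The recovered reads in genes numbered 15617407 in KO7, 16109031 in WT5, 16836966 in WT7, 16908863 in WT3, 19332336 in KO4, 19473512 in KO8, 20597350 in WT8 and 23437343 in KO5. The 10 genes with most reads took between 6.73% and 7.57% of each library. No row lacked a gene ID, and no column of per-sample values was left unused.

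The column headers number the libraries WT3, WT5, WT7 and WT8, and KO4, KO5, KO7 and KO8, whereas the labels number the mice from 1 to 4 in each genotype. Columns were therefore assigned to a genotype only, and the header numbers cannot be tied to the label numbers. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over genes was 12.1, between WT3 and KO7.

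The table lists 55487 genes, of which 51733 carried a symbol. Symbols for others came from GENCODE M21, the annotation of GRCm38, after which 55394 had one. Gene positions and types are from the same annotation, which held 55141 of the IDs. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), a pseudocount of 1, for the 16352 genes with a mean of at least 10 normalized counts over the 8 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum and no covariate. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. The level of Gsdme was compared by a two-sided exact permutation test of mean log2 values over the 70 assignments of libraries to genotypes, for which the smallest p is 0.0286.

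A set of 43 gene lists was fixed before the data were examined, as were the tests between genotypes and all alternatives but the 2 named as later choices. Tests of explanations that were chosen later are named as such where they are given. Of the 953 list symbols, 7 had no match. Lists with at least 5 tested members, 42 of the 43, were tested with camera at its preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. The haemoglobin and erythroid list had too few tested members. The list score of a library is the mean log2(normalized count + 1) over tested members, compared by the exact permutation test. Principal components were computed on the centred values of the tested genes.

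The genes named were chosen by rule. Gsdme came first, then the other tested gasdermin genes. Up to 15 called genes per direction whose 4 libraries did not overlap those of the other genotype were to follow, leaving out gene models, pseudogenes and antigen receptor variable segments. Because fewer than 5 such genes existed in each direction, the 10 of smallest unadjusted p per direction took their place. For each list, called members or else the 2 members of highest mean were named. Igkv10-96, excluded by the rule as a variable segment, is named because it was the sole call. Genes named beyond the rule are described as chosen after their values were seen. Results of some genes that the rule names are not reported here.

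The alternatives tried were pseudocounts of 0.5 and 5, no filter beyond a value above 0, a mean of at least 50, TMM scaling, quantile normalization, array quality weights, robust empirical Bayes, an edgeR 4.0.16 quasi-likelihood test and a DESeq2 1.42.0 Wald test on the recovered reads, a fold minimum, an adjusted p under 0.1, other list tests, a median in place of the mean in list scores, the 500 most variable genes for principal components, and each library left out in turn. The edgeR test on recovered reads called 1 gene higher and 0 lower, and DESeq2 called 8 higher and 1 lower. Leaving out KO4 and KO5 together, and adding the B cell and follicle score as a covariate, were chosen after the data were seen.

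The limma step was tested on simulated data for the Gsdme_KO against WT comparison, drawn for the 16352 genes from the real means, dispersions and depths, with 200 changed genes in each of 5 runs. It called 44.2% of the genes changed 2-fold, 84.2% of those changed 4-fold and 94.5% of those changed 8-fold, and 0.0458% of unchanged genes. Simulated genes varied independently, unlike the genes of a cell type in tissue. With 200 changed genes per run, the adjusted p threshold is also easier to reach than where few genes are called, so these shares may be too high for the real data. Counts per gene do not show which exons were read, and near-identical genes may share reads.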

Results

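Irinotecan is a topoisomerase I inhibitor whose use is limited by intestinal injury, and Gsdme encodes gasdermin E, a pore-forming protein that is opened by caspase cleavage. The series compared gene expression in the ileum of irinotecan-treated mice with and without Gsdme. Bulk poly(A) RNA-seq gave 4 WT and 4 Gsdme_KO libraries, 1 per mouse, with 15617407 to 23437343 reads in genes. No untreated mice were analysed here, so the values describe genotypes under treatment and not the response to irinotecan. All values below are normalized counts unless stated.

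The targeted gene was measured first. Gsdme (ENSMUSG00000029821, chromosome 6, 50188888 to 50263862, minus strand, GRCm38) had 2851 ± 536 normalized counts in WT and 349 ± 242 in Gsdme_KO (SD, n = 4 each), or 12.3% of the WT mean. The 4 WT libraries held 3376 (WT3), 2169 (WT5), 3164 (WT7) and 2696 (WT8). The 4 Gsdme_KO libraries held 113 (KO4), 187 (KO5), 634 (KO7) and 464 (KO8), all below every WT library, from 123 to 520 recovered reads. The log2 difference in means was -3.32 (exact permutation p = 0.0286, two-sided, the smallest this design can give). In the test across all genes, Gsdme had an unadjusted p of 9.62e-05 and a limma adjusted p of 0.786, so it was not called there. Leaving out KO4 and KO5 together, a choice made after the data were seen, gave a log2 fold change of -2.37 with a limma adjusted p of 0.0275.

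The other gasdermins did not separate the genotypes. Gsdmd, the inflammasome effector, had 4995 ± 878 normalized counts in WT and 5357 ± 1060 in Gsdme_KO (SD, n = 4; limma adjusted p = 0.921). Gsdma was low, at 42.9 ± 8.92 and 29.6 ± 12.4 (limma adjusted p = 0.849). The neighbouring Gsdmc2, Gsdmc3 and Gsdmc4 on chromosome 15 ranged widely within each genotype. Gsdmc4 ran from 67.9 in WT8 to 4125 in WT5, and from 60.8 in KO4 to 8015 in KO5. These 3 paralogs are similar in sequence, so their separate values are uncertain. The list of gasdermins and inflammasome genes had 26 tested members, 15 with a positive and 11 with a negative log2 fold change (camera adjusted p = 0.939), and its median and mean were positive while camera pointed lower.

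**Figure D1:**
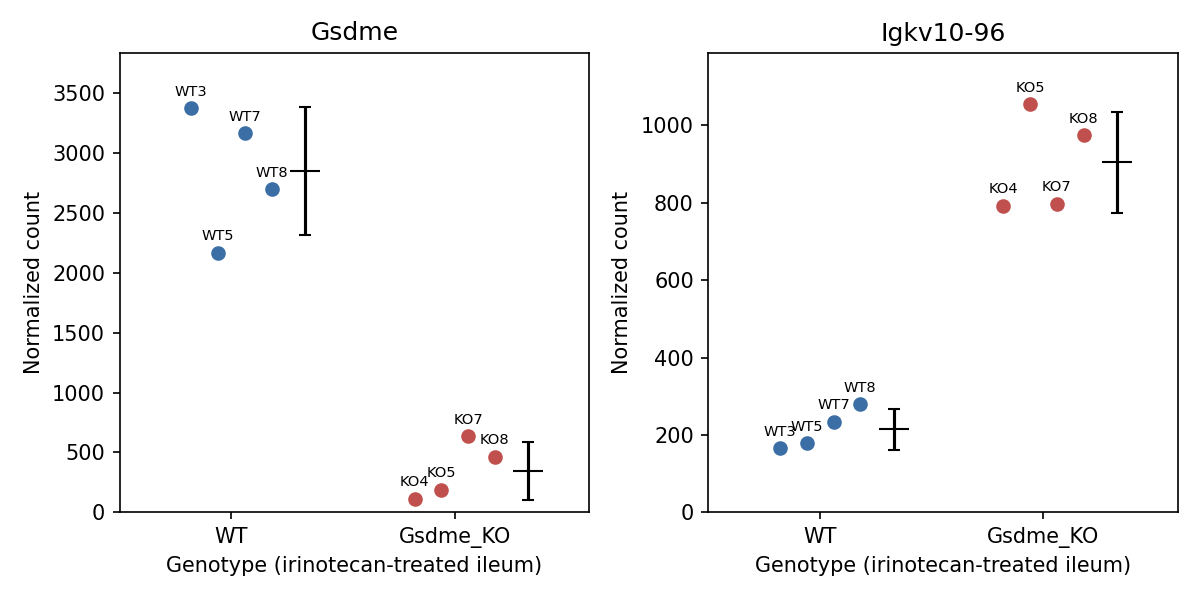
Normalized counts (y axis) of Gsdme and of Igkv10-96 in each library, by genotype (x axis), with the mean and SD of 4 libraries at the right of each group. Gsdme lay between 2169 and 3376 in WT and between 113 and 634 in Gsdme_KO, and Igkv10-96 between 166 and 280 in WT and between 792 and 1054 in Gsdme_KO.

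Across 16352 genes, 1 was higher in Gsdme_KO and 0 were lower by limma. The gene that rose was Igkv10-96 (ENSMUSG00000094420, chromosome 6, 68631963 to 68632442, minus strand, GRCm38), a variable segment of the immunoglobulin kappa light chain. It had 215 ± 52.7 normalized counts in WT and 904 ± 131 in Gsdme_KO (SD, n = 4), a log2 fold change of 2.09 (SE 0.182, limma adjusted p = 0.0237), higher in 4 of 4 libraries. Similar segments can share reads, so its own level is uncertain. The edgeR test on recovered reads also called 1 gene higher, Igkv10-96 (edgeR adjusted p = 0.0326), and 0 lower. DESeq2 called 8 higher and 1 lower, Gsdme being the lower gene (DESeq2 adjusted p = 2.24e-07). Its higher genes included the B cell genes Pax5, Bank1 and Fcer2a, of which Fcer2a had 701 normalized counts in KO4 and 402 in KO5 against 1 to 7 in the other 6 libraries. At an unadjusted p under 0.05, limma listed 427 genes higher and 290 lower, where 818 of either direction would come from chance alone. The total lay on either side of that number depending on the fit. Higher and lower genes numbered 982 and 915 without KO7, 649 and 336 without KO8, 610 and 635 with array weights, 699 and 275 by edgeR and 834 and 299 by DESeq2. They numbered 251 and 238 without KO4, 187 and 205 without KO5, 236 and 163 without WT7 and 256 and 170 without WT3. Quantile normalization turned this split to 346 higher and 402 lower. The genotypes did not overlap in 215 genes higher and 194 lower, 2.5% of those tested, against 2.86% by chance. The Igkv10-96 call ended in 7 of the 8 fits that left out 1 library, remaining only without WT8 (limma adjusted p = 0.02), while its log2 fold change stayed between 1.98 and 2.23 in these fits. The limma adjusted p was 0.0976 without WT3, 0.166 without WT5, 0.139 without WT7, 0.0511 without KO4, 0.152 without KO5, 0.0936 without KO7 and 0.181 without KO8.

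No other gene passed the threshold, and the genes named next are those of smallest unadjusted p. Among the 10 with higher means in Gsdme_KO, Slc66a3 had 317 ± 12.4 normalized counts in WT and 449 ± 34.3 in Gsdme_KO (SD, n = 4), a log2 fold change of 0.50 (SE 0.0899, limma adjusted p = 0.849). Rbm3, a cold-inducible RNA-binding protein, had 1938 ± 257 and 2666 ± 142, and Prex1, an activator of Rac, had 317 ± 40.4 and 526 ± 115. Rgs16, a regulator of G-protein signalling, had 22.0 ± 3.70 and 48.4 ± 16.4. The others were Sipa1l2, Slamf9, Tmem88, Osbpl5, Rpl35rt and Phtf1os, with log2 fold changes from 0.30 (Osbpl5) to 1.74 (Phtf1os). Rpl35rt is a retrocopy of a ribosomal protein gene and Phtf1os lies antisense to another gene, so reads of both are uncertain.

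Among the 10 with lower means in Gsdme_KO, Angptl4, a secreted inhibitor of lipoprotein lipase, had 1478 ± 460 normalized counts in WT and 615 ± 269 in Gsdme_KO (SD, n = 4), a log2 fold change of -1.32 (SE 0.313, limma adjusted p = 0.849). Topors, a ubiquitin and SUMO ligase known to bind topoisomerase I, had 690 ± 25.2 and 557 ± 32.0. Zbtb16, a transcription factor of innate-like lymphocytes, had a log2 fold change of -1.11 (SE 0.296). Nlrp9b, an NOD-like receptor of the intestinal epithelium, had 1154 ± 149 and 873 ± 69.9, and the pseudokinase gene Trib1 had 2810 ± 137 and 2139 ± 257. The others were Fpgt, Bmp8a, Lhfpl2, Ms4a12 and Adprm, with log2 fold changes from -0.77 (Bmp8a) to -0.43 (Lhfpl2). For all 20 of these genes the 4 libraries of each genotype did not overlap, which choosing the smallest p favours. Over all tested genes the share was 2.5%, against 2.86% by chance. DESeq2 called Slc66a3 (DESeq2 adjusted p = 0.00887) but none of the other 19.

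KO4 and KO5 stood apart from the other 6 libraries. The first principal component held 49.1% of the variance, with scores of 91.5 in KO4 and 46.5 in KO5, while KO7 (-35.3) and KO8 (-19.8) lay on the side of the WT libraries (-33.6 to -1.4). Neither the first (exact permutation p = 0.286, two-sided) nor the second component (14.6% of variance, exact permutation p = 0.371) separated the genotypes. The genes named next were chosen after their values were seen, and B cell genes were among those of highest loading. Ms4a1, which encodes CD20, had 1334 normalized counts in KO4 and 704 in KO5 against 2 to 20 in the other 6 libraries, and the complement receptor gene Cr2 had 1257 and 595 against 0 to 12. At the other end were transporters and enzymes of the enterocyte. Cubn, which encodes the ileal vitamin B12 receptor, had 167 in KO4 and 1002 in KO5 against 3633 to 10658 elsewhere, and Enpp7, an alkaline sphingomyelinase, had 7 and 30 against 433 to 2452.

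**Figure D2:**
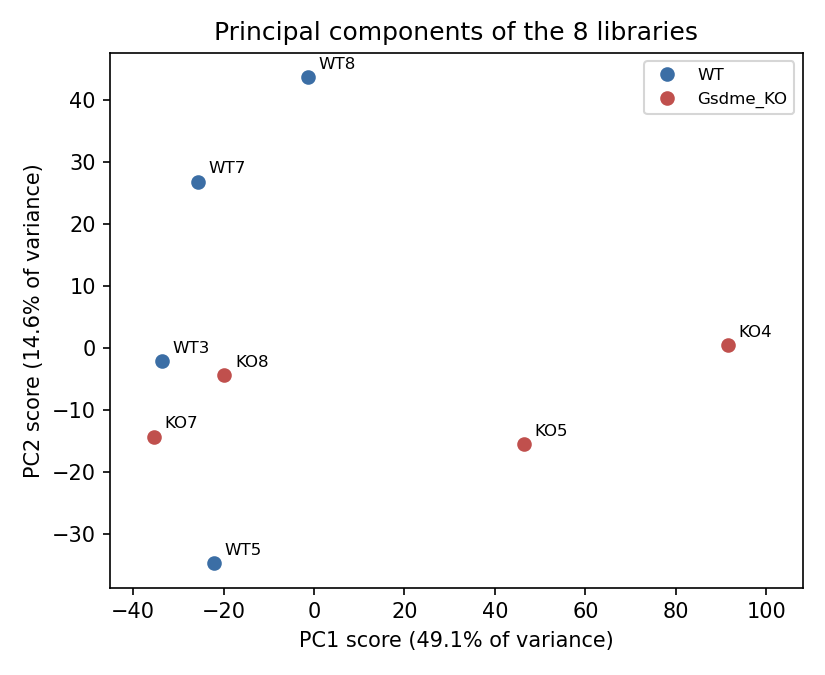
Scores of the 8 libraries on the first (x axis, 49.1% of variance) and second (y axis, 14.6% of variance) principal components of log2 normalized counts, each point 1 library colored by genotype. KO4 (91.5) and KO5 (46.5) lie at the right, and the other 6 libraries lie between -35.3 and -1.4 on the x axis.

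Lymphocyte, antigen presentation and myeloid gene lists made up most of the 11 lists that were higher in Gsdme_KO by camera. T cell and intraepithelial lymphocyte genes rose as a list (25 of 26 members with a positive log2 fold change, median 1.03, camera adjusted p = 9.59e-14), a call lost with an estimated correlation (adjusted p = 0.684). Their most abundant members, the granzyme genes Gzma and Gzmb, had 262 ± 160 and 133 ± 51.8 normalized counts in WT and 644 ± 236 and 332 ± 246 in Gsdme_KO (SD, n = 4), with Gzmb at 701 in KO4 and 205 to 213 in the other 3. MHC class II and interferon-gamma response genes rose (24 of 24 positive, median 0.86, camera adjusted p = 4.85e-09, adjusted p = 0.684 with an estimated correlation), with Cd74, the invariant chain, at 30000 in KO4, 18189 in KO5, 11413 in KO7 and 6654 in KO8 against 8026 ± 832 in WT (SD, n = 4). B cell and follicle genes rose (21 of 21 positive, median 2.06, camera adjusted p = 1.69e-08, adjusted p = 0.684 with an estimated correlation). Cd79a, a subunit of the B cell receptor, had 2029 in KO4 and 1240 in KO5, but 196 in KO7 and 129 in KO8, against 145 ± 25.2 in WT. Without KO4 the mean log2 fold change, here and below over the members tested in that fit, went from 1.00 to 0.64 for the T cell list, from 1.01 to 0.38 for the MHC class II list and from 2.24 to 1.36 for the B cell list.

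Cytokines and chemokines (23 of 25 positive, camera adjusted p = 1.44e-06), neutrophil genes (14 of 14, 6.91e-06), plasma cell genes (18 of 20, 0.000204), macrophage and monocyte genes (20 of 23, 0.00218) and type 3 lymphoid genes (10 of 12, 0.0451) also rose as lists. None of these 5 calls held with an estimated correlation (adjusted p = 0.684 to 0.709). Il33, an epithelial and stromal alarmin, had 3822 normalized counts in KO4 and 944 in KO5 against 251 to 637 in the other 6 libraries. Nos2, which encodes inducible nitric oxide synthase, had 7674 in KO4, but 936 to 1322 in the other 3 Gsdme_KO libraries and 1205 to 2941 in WT. The 2 most abundant plasma cell genes, Igha and Igkc, had log2 fold changes of 0.20 and 0.21, and Maf, the most abundant type 3 lymphoid gene, of -0.39. Outside the leukocyte lists, tuft cell genes (17 of 17 positive, camera adjusted p = 3.24e-05), endothelial and lymphatic genes (18 of 21, 0.000148) and fetal-like regenerating epithelium genes (18 of 20, 0.000308) rose, and none of these 3 calls held with an estimated correlation (adjusted p = 0.684 to 0.705). The most abundant tuft list member, Ptprc, is also expressed by leukocytes. WT8 had a tuft score of -0.89 relative to the WT mean, and without WT8 the mean log2 fold change of the tuft list went from 0.50 to 0.20 (camera adjusted p = 0.0469). The Ly6a gene of the fetal-like list had 27805 in KO4 and 10881 in KO5 against 2431 to 7152 elsewhere. Without KO4 the calls of the cytokine (camera adjusted p = 0.119), fetal-like (0.267), macrophage (0.489) and type 3 lymphoid lists (0.489) ended. The type 3 lymphoid call also ended without KO5 (0.0795), WT3 (0.134), WT5 (0.144) or WT7 (0.0798), with TMM factors (0.0504), with quantile normalization (0.0542) and with a mean of at least 50 (0.877). Its mean log2 fold change was 0.80 with all libraries, 0.39 without KO4 and 0.18 with a mean of at least 50. In the other fits named it lay between 0.61 (without WT5) and 0.80 (TMM factors). Without KO4 the mean log2 fold change also went from 1.14 to 0.64 for neutrophil genes and from 0.31 to 0.19 for endothelial and lymphatic genes, both still called.

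Mature enterocyte genes and 4 other lists were lower in Gsdme_KO by camera. Mature enterocyte genes fell as a list (29 of 30 members with a negative log2 fold change, median -0.54, camera adjusted p = 2.13e-07, adjusted p = 0.69 with an estimated correlation). Anpep, the brush border aminopeptidase N, had 24511 normalized counts in KO4 and 27493 in KO5, against 143100 in KO7, 105670 in KO8 and 121136 ± 26699 in WT (SD, n = 4). Irinotecan metabolism and transport genes fell (19 of 25 negative, median -0.48, camera adjusted p = 0.00845, adjusted p = 0.684 with an estimated correlation). Ces2e, a carboxylesterase of the family that activates irinotecan, had 5815 in KO4 and 7443 in KO5 against 12554 to 20073 in the other 6 libraries. Abcb1a, which encodes the drug exporter P-glycoprotein, had 3035 and 4506 against 10642 to 21034. Cholesterol biosynthesis genes (21 of 21 negative, median -0.23, camera adjusted p = 1.56e-06), tight junction genes (19 of 21, median -0.17, 0.000207) and enteroendocrine genes (16 of 23, median -0.16, 0.0225) fell by less. With an estimated correlation these 3 lists each had an adjusted p of 0.684. Epcam of the tight junction list had 46147 ± 5391 in WT and 38955 ± 5111 in Gsdme_KO, and Gcg, which encodes proglucagon, had 1999 ± 426 and 1421 ± 191 (SD, n = 4). The irinotecan call ended without KO4 (camera adjusted p = 0.154) or KO5 (0.0899), and the enteroendocrine call without WT8 (0.181), KO8 (0.0711) or KO4 (0.267), where its mean log2 fold change turned from -0.09 to 0.03, while the score difference over the members tested with all libraries kept its sign at -0.02. The enteroendocrine mean log2 fold change was -0.19 without KO5 and -0.04 without WT8. The mean of the mature enterocyte list went from -0.61 to -0.24 without KO4 and to -0.94 without KO7, and that of the cholesterol list from -0.25 to -0.13 and -0.37.

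The list scores showed where these differences lay. The B cell and follicle score was 4.86 above the WT mean in KO4 and 4.31 in KO5, but -0.12 in KO7 and -0.11 in KO8. For mature enterocyte genes the scores relative to the WT mean were -1.72 in KO4, -1.03 in KO5, 0.37 in KO7 and -0.06 in KO8. No list score passed the exact permutation test (0 of 42 lists, smallest adjusted p = 0.8), in which 0.0286 is the smallest p possible, so that 1 list alone could not pass after adjustment, and fry called no list (smallest adjusted p = 0.718). Of the list members, 0 were called over all genes tested, and 1, Angptl4 of the fatty acid oxidation list, was called when adjusted over the list alone (limma adjusted p = 0.0487). Without KO4 and KO5, an alternative chosen after the data were seen, 2 of the 11 higher lists (T cell, adjusted p = 0.00139, and tuft, 1.2e-05) and 2 of the 5 lower lists (tight junction, 0.00974, and enteroendocrine, 0.0223) were called by camera. The mean log2 fold change there was 0.34 for the T cell list, against 1.00 with all libraries, and -0.15 against -0.24 for tight junction genes. It was 0.62 against 0.50 for tuft cell genes and -0.09 in both for enteroendocrine genes. For tight junction genes it was also -0.15 with all libraries when only genes with a mean of at least 50 were tested. Without KO4 alone, 7 lists were called higher instead of 11, and 8 were called lower instead of 5 without KO5 or without KO7.

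**Figure D3:**
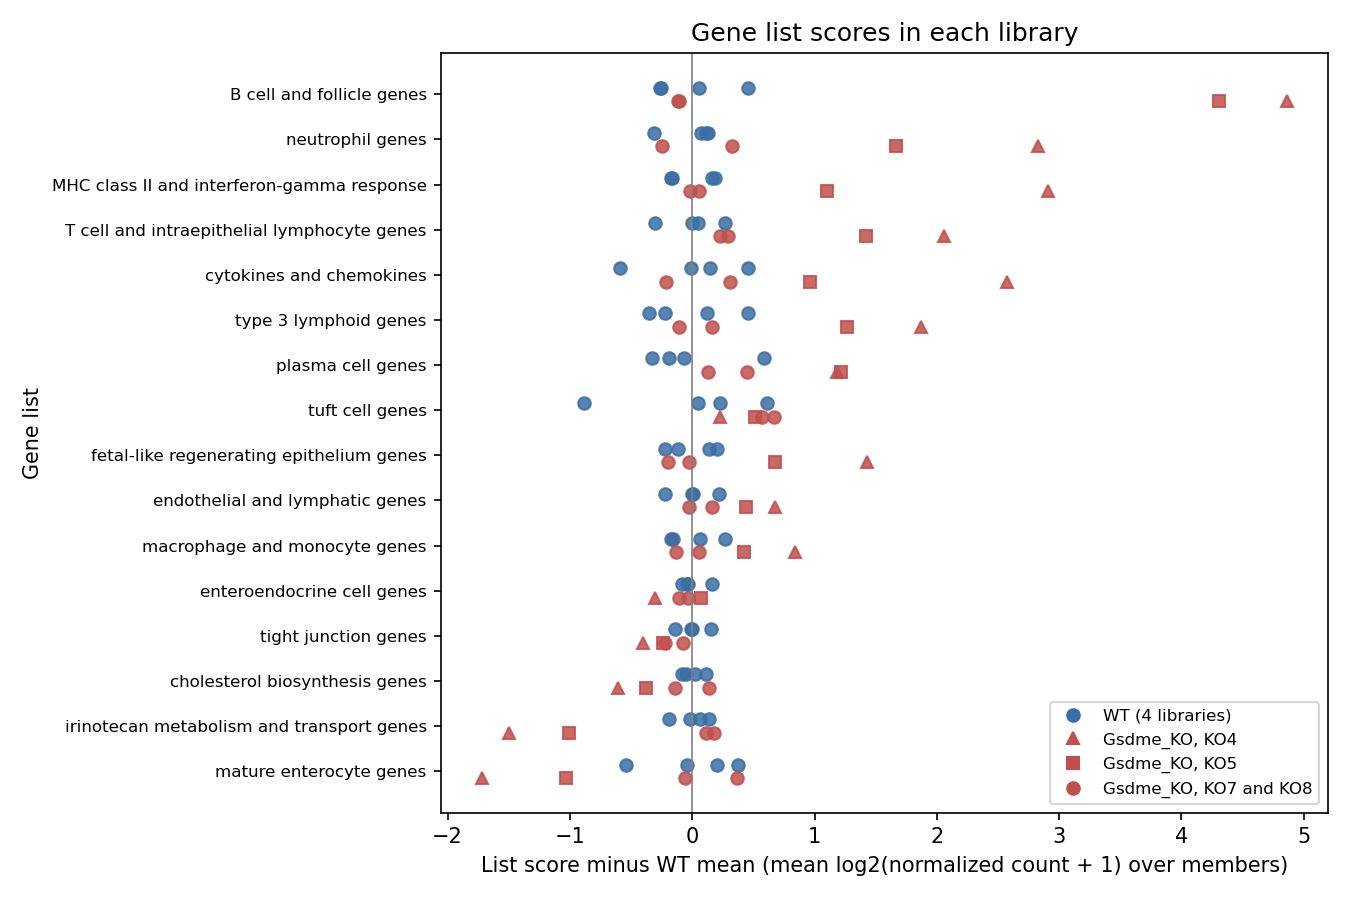
List score of each library minus the WT mean (x axis, mean log2(normalized count + 1) over members) for the 16 gene lists called by camera (y axis). Circles in blue are WT, and red triangles, squares and circles are KO4, KO5 and the other 2 Gsdme_KO libraries, with B cell and follicle scores of 4.86 in KO4 and 4.31 in KO5.

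The remaining 26 lists were not called. Among DNA damage and renewal genes were p53 target genes (10 of 28 positive, camera adjusted p = 0.236), cell cycle genes (15 of 33, 0.7) and crypt base stem cell genes (11 of 23, 0.378). Cdkn1a, the p53-induced cell cycle inhibitor, had 10326 ± 2263 normalized counts in WT and 10686 ± 956 in Gsdme_KO, and Top2a, a proliferation marker, had 1968 ± 604 and 1920 ± 198 (SD, n = 4). Secretory and regional epithelial lists gave camera adjusted p of 0.484 (Paneth cell), 0.149 (goblet cell), 0.118 (ileal bile acid handling), 0.875 (villus tip enterocyte), 0.377 (proximal small intestine) and 0.894 (large intestine). The Paneth cell lysozyme gene Lyz1 had 57361 ± 21180 in WT and 56051 ± 23878 in Gsdme_KO. Inflammatory lists without a call were antimicrobial and acute-phase epithelial genes (0.238), type I interferon-stimulated genes (0.259), and mast cell and eosinophil genes (0.0909). Reg3g, an antimicrobial lectin gene, had 181666 in KO4, but 13789 to 29763 in the other 3 Gsdme_KO libraries and 41527 to 95493 in WT. Leaving out 1 library brought calls by camera for p53 targets (lower, adjusted p = 0.0212 without KO4, 0.0176 without KO5, 0.0441 without WT7), cell cycle genes (lower, 7.96e-08 without WT5) and crypt base stem cell genes (lower, 0.0261 without KO5, 0.0266 without WT5). For p53 targets the mean log2 fold change was -0.05, and it was -0.18 both without KO4 and KO5 together (camera adjusted p = 2.21e-05) and with the B cell score as a covariate (1.51e-05), each chosen after the data were seen, but 0.00934 without KO8. All of these calls, and those that follow, used the preset correlation of 0.01, and with all libraries no list was called with an estimated correlation (smallest adjusted p = 0.684) or by fry (0.718). Leaving out 1 library also brought calls for Paneth cell genes (higher, 0.0163 without WT7), goblet cell genes (lower, 0.00236 without KO5, 0.041 without KO7, 0.0361 without WT8) and bile acid handling genes (lower, 0.0175 without KO7, 0.0444 without KO8, 0.0256 without WT8). It also did so for antimicrobial genes (higher, 0.0417 without KO8), mast cell and eosinophil genes (higher, 0.0492 without KO7, 0.014 without WT3, 0.0467 without WT5) and type I interferon-stimulated genes, which were lower without KO4 (0.0358) and higher without KO7 (0.00171).

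Stress and metabolic lists gave camera adjusted p of 0.715 (unfolded protein and integrated stress response), 0.894 (NRF2 and glutathione), 0.0548 (PPAR-alpha and fatty acid oxidation), 0.913 (circadian clock), 0.659 (immediate-early and heat-shock) and 0.939 (mitochondrially encoded). Stromal and neighbouring tissue lists gave 0.16 (fibroblast and matrix), 0.259 (smooth muscle), 0.907 (enteric neuron, glia and interstitial cell), 0.592 (pancreatic acinar) and 0.0955 (adipose and mesenteric). Sex-linked genes gave 0.85, and Ddx3y on the Y chromosome had 814 to 1057 normalized counts in every library, while Xist had at most 2.7. Genes next to Gsdme on chromosome 6 did not differ as a list (22 of 41 positive, median 0.03, camera adjusted p = 0.894). For the immediate-early, sex-linked, enteric neuron and mitochondrial lists the median and the mean of the log2 fold changes, or the test, differed in sign. Calls by camera appeared for fatty acid oxidation genes (lower, adjusted p = 0.00194 without KO7, 0.0417 without KO8, 0.0473 without WT7, 0.000371 without WT8), adipose genes (higher, 4.31e-06 without KO5, 0.0372 without WT5), fibroblast genes (higher, 0.018 without KO7, 0.000407 without WT8), smooth muscle genes (lower, 0.000105 without KO5) and unfolded protein response genes (higher, 0.048 without WT5). With no filter on means, fatty acid oxidation genes (lower, 0.0483) were called, as were haemoglobin and erythroid genes (lower, mean log2 fold change -0.70, 0.00181), which otherwise had too few tested members. In the alternatives chosen after the data were seen, further uncalled lists were called at the preset correlation. Without KO4 and KO5 these were type I interferon-stimulated (1.2e-05), antimicrobial (0.00977), immediate-early (0.00863), villus tip (0.0177) and smooth muscle genes (0.0199), all lower, and mitochondrially encoded (0.0033) and adipose genes (3.4e-05), both higher. With the B cell score as a covariate they were type I interferon-stimulated (0.000222) and immediate-early genes (0.013), both lower, and mitochondrially encoded (0.00172), adipose (0.00297) and circadian clock genes (0.0298), all higher.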

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

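Within each genotype, a single library was looked for whose gap to the nearest other as a share of the range of the 4 values was above Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Among 302 such groups, 12 had one, against 15.1 expected. The tests of KO4 and KO5 and of the residual Gsdme reads were chosen after the results were seen. In WT, the share of the range was 0.845 for Gsdmc3 (WT8 lowest), 0.872 for H2-Aa (WT7 lowest), 0.83 for Plvap (WT5 highest) and 0.872 for the neutrophil score (WT3 lowest). In Gsdme_KO, KO4 was lowest for Topors (0.88), Slc12a2 (0.881) and Mylk (0.909) and highest for Nos2 (0.836) and Gzmb (0.969). KO5 was lowest for Car3 (0.929) and for the adipose and mesenteric score (0.851), and KO7 was lowest for the cell cycle score (0.882).

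Igkv10-96 was the sole gene called. Of the 35 splits of the 8 libraries, 1, the genotype split itself, called as many as 1 gene. The highest of the other splits was 0. That share lies under 0.05, which argues against chance assignment, but it is the smallest that 35 splits can give. It rests on a single gene whose call ended in 7 of the 8 fits without 1 library. Over all genes, the share not overlapping between genotypes was 2.5%, against 2.86% by chance. Chance is therefore not excluded. More plasma cell RNA in Gsdme_KO is argued against, since the ratio of Igkv10-96 to Igkc still differed by 1.88 on the log2 scale, with 0.342% to 1.05% in WT and 1.6% to 2.96% in Gsdme_KO. Counted reads moving among Igkv10-94, Igkv10-95 and Igkv10-96 are argued against by the sum of these segments, which differed by 1.97 on the log2 scale. The sum cannot show reads gained from other kappa segments or from reads that were left uncounted. A chromosome 6 segment inherited together with the Gsdme allele stays open as a possible explanation, because Igkv10-96 lies 18.4 Mb from Gsdme, and the odds ratio of an unadjusted p under 0.05 within 25 Mb was 1.22 (14 of 271 genes, Fisher exact p = 0.448, 95% interval 0.654 to 2.1). Of 72 tested kappa segments, which all lie in 1 locus (67555497 to 70723927), 3 did not overlap between genotypes, near the 2.06 expected by chance. These were Igkv9-120, Igkv15-103 and Igkv10-96, all higher in Gsdme_KO. Of the 72, 50 had a positive log2 fold change, and 8 were higher and 0 lower at an unadjusted p under 0.05 by limma. Segments measured in the same libraries are not independent, so these counts were not tested. DESeq2 also called Igkv15-103 (DESeq2 adjusted p = 0.00724). An effect of Gsdme deficiency itself stays open, as untested.

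The 16 called lists are not beyond what other splits of the libraries give, since 20 of the 35 splits called as many, with at least 6 in every split and up to 26 in another, that of KO4, KO5, WT7 and WT8 against the rest. In the B cell and follicle score, 2 of the 4 Gsdme_KO libraries, KO4 and KO5, exceeded all WT libraries. For that score, this goes against a genotype effect shared by all 4 Gsdme_KO libraries, though the rule was written after these scores were seen. The MHC class II score also had 2 above all WT libraries, but the T cell and neutrophil scores had 3. The tight junction and cholesterol scores had 3 below all WT libraries, the latter with 1 above. With a median over members, the T cell score had an exact permutation p of 0.0286 (adjusted p = 0.7). A shared effect on these other lists was not excluded. An effect of genotype in only some mice was not tested. Lymphoid follicles in the KO4 and KO5 tissue pieces are a candidate explanation that these data do not decide. Of 7 follicle genes outside the B cell list, 85.7% were above the other 6 libraries in both. These genes were chosen after KO4 and KO5 were seen to stand apart, and Glycam1 was among those of highest loading on the first component. The same share over all tested genes was not determined, so 85.7% has no baseline. The clearest were Marcksl1 (8454 and 6256 against 1902 to 3392) and Glycam1 (44.2 and 78.9 against 0). For Chst4 the margin was small in KO5 (826 against 800 in WT8), and Coch did not pass (6.76 in KO5 against 9.08 in WT3). The median of villus tip genes stood above that of mature enterocyte genes, both relative to WT, by 0.955 in KO5 and 1.51 in KO4. These gaps lay beyond the SD over villus tip genes (0.623 and 0.894) and the WT gaps (-0.171 to 0.256). This argues against dilution of enterocyte RNA by other cells as the whole cause only so far as the villus tip genes are read from enterocytes alone. That was not tested, and Lgals3 of that list was higher in KO4 (20987) and KO5 (29507) than in WT (mean 11540). Dilution as a part of it cannot be told apart from lower enterocyte expression, because the spread over mature enterocyte genes was 1.46 times the highest of a WT library in KO5 and larger in KO4, where Epcam stood at 34389 against a WT mean of 46147 while Anpep stood at 24511 against 121136.

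The Gsdme reads left in Gsdme_KO differed 5.59-fold between KO7 and KO4. Less enterocyte RNA in the libraries with fewer Gsdme reads is a possible explanation, since dividing by each library's enterocyte level brought the ratio of highest to lowest down to 1.31. The same division widened the WT range from 1.56-fold to 2.34-fold, which goes against it. With 4 values, and both measures shifted in the same libraries, the 2 readings cannot be told apart.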

How the results depend on the processing

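No paired analysis was possible because the column headers carry other numbers than the labels, so a replicate block was not run. The labels number the mice within each genotype and name no pairs. Leaving out KO4 and KO5 together and the B cell score covariate were chosen after the data were seen. The difference in Gsdme kept its direction with other pseudocounts, TMM factors and each library left out, from -2.88 without KO4 to -3.71 without KO7. Pseudocounts, filters, scalings, array weights, robust fitting, a fold minimum, an adjusted p under 0.1 and edgeR left 1 gene higher and 0 lower, with Igkv10-96 at an adjusted p of 0.00286 to 0.0326. DESeq2 called 8 genes higher and 1 lower, 3 of them among the named genes (the cause was not tested). At an unadjusted p under 0.05, 427 genes were higher and 290 lower, against 776 and 509 with no filter, 279 and 220 with a mean of at least 50, 610 and 635 with array weights, 699 and 275 by edgeR, 834 and 299 by DESeq2, 167 and 278 without KO4 and KO5 and 184 and 272 with the B cell covariate. Leaving out 1 library gave 0 to 1 genes higher, 0 lower and 0 to 1 named genes called, with fewer samples. It gave 7 (without KO4) to 14 (without KO7) lists higher and 5 to 8 lower (8 without KO5 and without KO7). Camera with an estimated correlation called 0 lists higher and 0 lower, as did fry. Without KO4 and KO5, 0 genes were higher and 1, Gsdme, was lower, and 4 lists were higher and 8 lower. With the B cell covariate, 2 genes were higher (Igkv10-96 and mt-Atp6) and 1 lower (Gsdme), and 5 lists were higher and 5 lower. No list score passed under any setting (smallest adjusted p = 0.32, without KO7), which says nothing of stability, since the smallest exact p possible is 0.0286, or 0.0667 without KO4 and KO5, before adjustment over 42 lists. The first component held 49.1% to 52.4% of the variance. Among lists called in at least 1 of the 2 fits compared, mean log2 differences over the members tested in each fit changed sign for some, for which the cause was not tested, and further lists called in neither also changed sign. Without KO4 these were type I interferon-stimulated genes (-0.0783, called; up to 0.381 without KO7) and enteroendocrine genes (0.0262; down to -0.192 without KO5). Without KO4 and KO5 they were type I interferon-stimulated (-0.219, called), antimicrobial (-0.372, called) and immediate-early genes (-0.294, called), and, no longer called, cytokines (-0.0258), fetal-like (-0.112), mature enterocyte (0.155), irinotecan metabolism (0.142), macrophage (-0.036) and type 3 lymphoid genes (-0.00679). Over the members tested with all libraries, score differences there were 0.0454 for cytokines, 0.0298 for type 3 lymphoid genes and -0.114 for the B cell list (2.24 with all libraries), so the sign of these 3 depends on the members; enteroendocrine genes had -0.0237 without KO4. With the covariate they were type I interferon-stimulated (-0.224, called) and immediate-early genes (-0.276, called), and, no longer called, fetal-like (-0.111), mature enterocyte (0.147), irinotecan metabolism (0.121) and macrophage genes (-0.0454). In simulation, with 200 changed genes per run, 44.2% of genes changed 2-fold and 94.5% of those changed 8-fold were called. Gsdme, with a log2 fold change of -3.32, was not called in the real data (limma adjusted p = 0.786). Large changes can thus be missed too with 4 libraries per genotype, and the simulated shares may overstate what could be detected here.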

Other observations

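All genes and tests in this part were chosen after their values were seen, except the test on heavy chain segments. Ubd, which encodes the ubiquitin-like modifier FAT10, had 3623 normalized counts in KO4 against 40 to 234 elsewhere, Tgtp1, an immunity-related GTPase gene, had 1859 against 33 to 134, and Cxcl9, a chemokine gene, had 2698 against 89 to 328. Ifng itself had 52.5 in KO4 and at most 5.5 elsewhere. KO5, which shared the B cell genes of KO4, had 234 for Ubd and 328 for Cxcl9. The score of the MHC class II and interferon-gamma response list was 2.91 above the WT mean in KO4 and 1.10 in KO5.

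Gsdmc genes and some other epithelial genes were low in the same WT library. WT8 had 72 normalized counts of Gsdmc2 and 68 of Gsdmc4, and in the same library Pla2g4c, a cytosolic phospholipase A2 gene, had 918 and Mptx1, a mucosal pentraxin gene, had 6. KO5 had the highest values of all 4 genes, with 8526 for Gsdmc2, 8015 for Gsdmc4, 59587 for Pla2g4c and 339 for Mptx1. KO4 combined low Gsdmc2 (190), Gsdmc4 (61) and Pla2g4c (3772) with an Mptx1 value of 230.

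Naip6, which encodes a sensor of bacterial flagellin, had 0 normalized counts in KO5, 814 in KO4 and 1474 in WT7, against 3171 to 3802 in the other 5 libraries. The nearby pseudogene Naip3-ps1 had 35 in KO5, 77 in KO4 and 194 in WT7, against 444 to 643 in the others. Naip5 had 5829 in WT7 and 2512 to 4498 in the other 7 libraries, and Naip1 stayed between 3374 and 4169. All 4 genes lie on chromosome 13 between 100211739 and 100452869 (GRCm38), and as close relatives their separate values are uncertain. Plscr1l1, a phospholipid scramblase relative on chromosome 9, had 0 in KO4 and 1 in KO5 against 88 to 172 elsewhere. The mitochondrial gene mt-Atp6 had 1166 in KO7 and 1134 in KO8 against 419 to 616 in the other 6 libraries.

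One hypothesis for Igkv10-96 was different antibody repertoires between cages or litters, which could also separate heavy chain segments on chromosome 12. Of 78 tested Ighv segments, 0 (0%, exact 95% upper bound 4.62%) did not overlap between genotypes, where 2.23 would by chance. By the rule set beforehand, a share under the 2.86% that chance gives was to count against this hypothesis, and 0% met it. The bound was not part of that rule. With 78 segments it lies above 2.86% even at a count of 0, so it could not have excluded the hypothesis. The hypothesis is therefore neither borne out nor excluded. Of the 78 segments, 67 had a positive log2 fold change, 9 with an unadjusted p under 0.05 by limma, against 1 negative at that threshold. Segments measured in the same libraries are not independent. The plasma cell score stood 1.19 above the WT mean in KO4 and 1.21 in KO5, against 0.45 in KO7 and 0.13 in KO8. These counts therefore do not show a shift shared by all Gsdme_KO libraries.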
